A study of Rattus norvegicus with 15 samples.

How the data were processed

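The series holds 15 RNA-seq libraries of liver from Wistar rats. Per the labels, the livers were taken after 24 hours of refeeding, on the first day of weight regain, and were flash frozen. The rats had been sedentary or had run on a treadmill while they lost weight and kept it off, and were then fed ad libitum or, in 1 sedentary group, an energy gap-matched diet. The labels do not define that diet. The 3 groups of 5 libraries were sedentary ad libitum, exercised ad libitum and sedentary gap-matched, here called sedentary, exercised and gap-matched. Columns were assigned to groups by the column name that each label gives, and no value in the table checks this. The labels number the libraries within each group and do not state that each came from a separate animal, so the p-values measure only the spread between these samples.

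The deposited values were FPKM, fragments scaled by gene length and by the mapped fragments of the library, 1 value per Ensembl gene and library. Trimmomatic, Cufflinks and the rat build Rnor_5.0 were named in the submitters' processing notes, without versions. The aligner and any filters were not given in the sources used here. Gene names were taken from the deposited table itself, because none of its identifiers matched the gene table at hand. The table held 26407 entries, of which 2 repeated an identifier and were dropped. No name was given for 5795 genes, and 27 names had been turned into calendar dates by a spreadsheet, so these genes could not be named. Of 971 entries that shared a symbol with a more abundant entry, only the more abundant one stood for that symbol. The number 999999999 stood in place of a value for Alb in 11 libraries and for Slc27a2 in 2 libraries, and both genes were left out. No gene coordinates or lengths of the build were at hand. FPKM from genes with near-identical copies are uncertain, because reads can be shared between copies. This applies, among others, to the metallothioneins, the globins, the Cyp2b and Cyp3a enzymes and genes named only by a clone or locus number. Which other genes it touches, for example in the ribosomal list or Gapdh and Hspa8, was not checked.

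Read totals were not among the values used here, so absolute depth is unknown and no counting interval can be given. Relative depth was estimated from genes with a mean FPKM under 0.3, whose values step by single fragments. The commonest ratio of their values between a library and the first sedentary library gives the ratio of depths, in bins of 0.04 on the log2 scale.

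Values were analysed as log2(FPKM + 1), without further scaling, for the 11216 genes with a mean of at least 1 FPKM over the 15 libraries. This scale understates the fold difference of genes near 1 FPKM. The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with a mean trend in the variance, and the 3 differences between groups were tested on both sides. Adjusted p-values are Benjamini-Hochberg values within a comparison, and a gene passed at an adjusted p under 0.05. Lists of genes were tested with camera of the same package with a preset correlation of 0.01, adjusted over the 32 lists with at least 3 tested members. Each list test was repeated with a correlation estimated from the data, and with it no list passed in any of the 3 comparisons. Of the 35 lists, those of skeletal muscle markers and of mitochondrially encoded transcripts had 0 tested members. The exocrine pancreas list had 1, Cela1, whose log2 difference of −1.11 between exercised and gap-matched rats did not pass (limma adjusted p = 0.163).

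The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule named, in each comparison, the 12 genes with the largest log2 difference in each direction among those that passed. It added up to 4 members with the smallest p of each list described, and a panel fixed in advance. The panel included Acly, Acaca, Fasn, Scd1, Elovl6, Me1, Srebf1, Mlxipl, Pklr, Pck1 and Cpt1a, with G6pc, which was not named in the table. The text gives the genes of most interest among these.

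The alternatives were pseudocounts of 0.1 and 0.5, no filter and filters at 0.1 and 5 FPKM, and 3 scalings (to the same sum, by the median of ratios, and quantile normalization). They also included fits of only the 2 groups compared, without the mean trend, with a robust trend, with library weights, with the replicate number as a block and without each library in turn. A threshold of 0.1 and the fry set test were tried too. After the data had been seen, a covariate made from the deviations within groups, an exact permutation test of each list's mean per library, and the sum and median-of-ratios scalings for all lists were added. Relations between lists within groups were tested with 100000 permutations within groups, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

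The gene test was tested on simulated data with the spread of the 11216 genes and 200 changed genes. A log2 change of 0.5 was recovered for 52% of 50 genes in exercise minus sedentary, 54% in gap-matched minus sedentary and 56% in exercise minus gap-matched. At a log2 change of 1 the shares were 84%, 88% and 96%. False calls made up 0.595%, 3.47% and 3.83% of the calls in the same order. The simulated genes varied independently of each other, and genes of low FPKM were not among those changed. These shares therefore do not carry over to libraries whose genes vary together, nor to genes of low FPKM.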

Results

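The data are transcript levels of 15 rat liver libraries in 3 groups of 5, measured on the first day of weight regain and deposited as FPKM. Relative to the first sedentary library, depth ran from 0.678 to 1, with means of 0.854 ± 0.122 (SD, n = 5) in sedentary, 0.897 ± 0.058 in exercised and 0.908 ± 0.079 in gap-matched rats. Between 11009 and 11365 genes reached 1 FPKM in a library. Correlations of the log2 values between libraries of 1 group lay between 0.967 and 0.984. Differences below are on the log2(FPKM + 1) scale with their standard error, and FPKM are means ± SD of 5 libraries.

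The first comparison set exercised against sedentary rats, both refed ad libitum, and so addresses how exercise during weight loss and its maintenance relates to lipid synthesis transcripts in early regain. Of 19 lipogenesis members 11 were lower in exercised rats, and the list had an adjusted p = 0.104 with an estimated correlation. Fasn, the fatty acid synthase, fell by 1.63 ± 0.26 on the log2 scale, from 1170 ± 272 to 377 ± 96.7 FPKM (limma adjusted p = 0.00275), and all 5 exercised libraries lay below the lowest sedentary library. Acly, which makes cytosolic acetyl-CoA, fell by 1.30 ± 0.21, from 1429 ± 239 to 585 ± 129 FPKM (limma adjusted p = 0.00264). In the cholesterol list 13 of 24 were lower, and 2 of 12 gluconeogenesis, 2 of 34 fatty acid oxidation and 9 of 35 drug metabolism genes were higher. Each of these lists passed with the preset correlation, with an adjusted p = 0.104, 0.463, 0.398 and 0.104 with an estimated correlation. Of 11216 genes tested, 282 were higher and 366 lower in exercised rats at a limma adjusted p under 0.05, and 20 of the higher and 33 of the lower differed by more than 2-fold. With libraries rescaled to the same sum, 161 were higher and 314 lower, so that lower genes made up 66.1% of the calls against 56.5%.

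Of 19 tested members of the de novo lipogenesis list, 11 fell, 0 rose and the others did not pass, and 16 were lower when adjusted over the list alone. The median difference was −0.66, and camera gave a Benjamini-Hochberg adjusted p of 8.8e-14, against an adjusted p = 0.104 with an estimated correlation. Gpam, the acyltransferase of the first step of glycerolipid synthesis, fell by 2.37 ± 0.31, from 256 ± 118 to 44.9 ± 9.15 FPKM (limma adjusted p = 0.000652). Pnpla3, which encodes a lipid droplet protein, fell by 2.40 ± 0.31, from 958 ± 144 to 183 ± 43.3 FPKM (limma adjusted p = 0.000611). Srebf1, a transcription factor of lipogenic genes, fell by 0.68 ± 0.16 (limma adjusted p = 0.0197), a call lost without sedentary library 2 (0.0542) or exercised library 1 (0.051). The elongase Elovl6 fell by 1.22 ± 0.29 (limma adjusted p = 0.0209), a call lost in 4 of the 10 fits that left out a library, those without sedentary library 1 (0.0514), 2 (0.0517) or 5 (0.0533) and exercised library 1 (0.0589). Pklr fell by 0.77 ± 0.19 (limma adjusted p = 0.0297), a call lost in 7 of the 10 fits, at up to 0.0723, and under 2 of the 3 scalings. Among the panel genes that did not pass, Scd1 differed by −0.53 (limma adjusted p = 0.177), Me1 by −1.17 (0.079), Acaca by −0.41 (0.17) and Mlxipl by −0.34 (0.134).

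**Figure D1:**
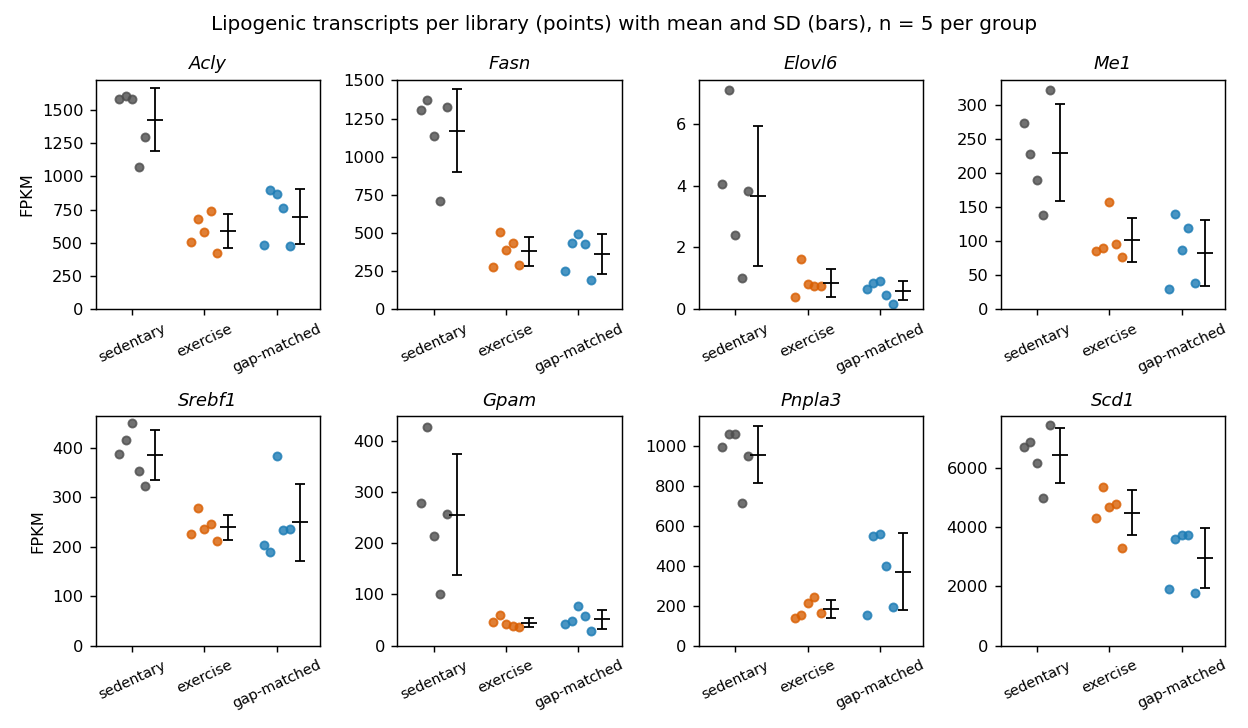
FPKM of 8 lipogenic genes in each of the 15 libraries, by group, with the mean and SD of 5 libraries. Fasn had means of 1170 FPKM in sedentary, 377 in exercised and 359 in gap-matched rats, and all 10 exercised and gap-matched libraries lay below the sedentary ones.

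Of 24 tested members of the cholesterol synthesis and uptake list 13 fell and 0 rose, and adjusted over the list alone 18 were lower and 1 higher. The median difference was −0.61, with a camera adjusted p of 7.4e-15 and an adjusted p = 0.104 with an estimated correlation. Insig1, an endoplasmic reticulum protein that retains sterol regulatory factors, fell by 1.68 ± 0.28, from 437 ± 77 to 145 ± 64.1 FPKM (limma adjusted p = 0.00366). Mvd, an enzyme of the mevalonate pathway, fell by 1.56 ± 0.18, Sqle, the squalene epoxidase, by 1.26 ± 0.16 and Fdps by 0.99 ± 0.15. Outside the lists, the acetoacetyl-CoA synthetase Aacs fell by 2.35 ± 0.21, from 26.1 ± 4.99 to 4.47 ± 1.58 FPKM, and the kinase Sgk2 by 2.15 ± 0.15, from 30.4 ± 4.81 to 6.03 ± 0.616 FPKM (limma adjusted p = 3.7e-05 and 2.1e-06). In the pentose phosphate list 2 of 9 members fell, among them Rpia by 0.81 ± 0.13, and adjusted over the list alone 5 were lower. The list had a median of −0.20, a camera adjusted p of 0.00126 and an adjusted p = 0.104 with an estimated correlation. In the glycolysis list 3 of 13 members fell, also when adjusted over the list alone. That list had a median of −0.15 and a camera adjusted p of 0.00536, with an adjusted p = 0.398 with an estimated correlation. Of 26 members of the triglyceride and lipid droplet list 3 fell, and adjusted over the list alone 5 were lower and 2 higher. They were Gpam and the droplet coat proteins Plin2, by 0.90 ± 0.20, and Plin3, by 1.26 ± 0.28. The list as a whole did not pass (median −0.02, camera adjusted p = 0.264).

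Of 12 tested members of the gluconeogenesis list 2 rose and 0 fell, and 6 were higher when adjusted over the list alone. The median was 0.44 and the camera adjusted p 0.00205, with an adjusted p = 0.463 with an estimated correlation. Pck1, the cytosolic phosphoenolpyruvate carboxykinase, rose by 1.86 ± 0.42, from 282 ± 151 to 1013 ± 459 FPKM (limma adjusted p = 0.0182, and 0.0528 without exercised library 1). Got1, the cytosolic aspartate aminotransferase, rose by 1.61 ± 0.23, from 103 ± 26.6 to 319 ± 101 FPKM (limma adjusted p = 0.00143). Among 36 genes of amino acid breakdown and the urea cycle 6 rose, and adjusted over the list alone 10 were higher and 1 lower. Slc25a15, the mitochondrial ornithine carrier, rose by 1.17 ± 0.11, from 98.4 ± 14.4 to 223 ± 27.2 FPKM (limma adjusted p = 3.7e-05), and Kmo by 0.44 ± 0.09. This list had a median of 0.21, a camera adjusted p of 0.00126 and an adjusted p = 0.547 with an estimated correlation. In the fatty acid oxidation list 2 of 34 members rose, also when adjusted over the list alone. Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 1.54 ± 0.27, from 27.9 ± 14.3 to 79.5 ± 27.6 FPKM (limma adjusted p = 0.0043). The list had a median of 0.21, a camera adjusted p of 0.000625 and an adjusted p = 0.398 with an estimated correlation. Of 35 genes of drug and steroid metabolism 9 rose and 0 fell, and 13 were higher when adjusted over the list alone. Cyp2b1 rose by 1.54 ± 0.33 and Cyp3a23/3a1 by 0.62 ± 0.14. The median was 0.20 and the camera adjusted p 0.000944, with an adjusted p = 0.104 with an estimated correlation. Of 16 bile acid genes 2 rose, and adjusted over the list alone 5 were higher and 1 lower. Amacr rose by 0.90 ± 0.17. The list had a median of 0.26 and a camera adjusted p of 0.0196, against 0.078 without sedentary library 5, and an adjusted p = 0.398 with an estimated correlation.

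Heat shock transcripts went both ways. Of 15 tested members 2 rose and 3 fell, also when adjusted over the list alone, and the list did not pass (median −0.15, camera adjusted p = 0.25). The small heat shock protein Hspb1 rose by 1.64 ± 0.24, from 29.5 ± 7.0 to 98.9 ± 47.6 FPKM, and the constitutive chaperone Hspa8 fell by 0.97 ± 0.15 (limma adjusted p = 0.00165 and 0.00189). The metallothioneins MT1 and Mt1a rose by 2.29 ± 0.33 and 1.78 ± 0.37, with reads that the near-identical copies may share. Of 11 tested cell cycle genes 3 fell, and 6 were lower when adjusted over the list alone. The median was −0.43 and the camera adjusted p 0.00126, with an adjusted p = 0.459 with an estimated correlation. Of 14 immediate early genes 2 fell, also when adjusted over the list alone, among them Jund by 0.60 ± 0.11. That list had a median of −0.32, a camera adjusted p of 0.00628 and an adjusted p = 0.398 with an estimated correlation.

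Some marker lists of liver zones and other cell types passed as higher in exercised rats with the preset correlation. The neutrophil, lymphocyte, stellate cell, cholangiocyte, erythroid and adipocyte lists did not pass (camera adjusted p from 0.178 to 0.9). Pericentral hepatocyte markers had a median of 0.29 with 1 of 12 higher (3 when adjusted over the list alone), and periportal markers 0.28 with 2 of 14 higher (4 over the list alone). Kupffer cell markers had a median of 0.30 with 0 of 13 passing, and endothelial markers 0.20 with 0 of 15 passing. Their camera adjusted p-values were 0.00765, 0.00721, 0.0196 and 0.00628 in this order. With an estimated correlation, the adjusted p = 0.459 for pericentral, 0.463 for periportal, 0.584 for Kupffer and 0.573 for endothelial markers. Without sedentary library 5 the pericentral (camera adjusted p = 0.0586), Kupffer (0.257) and endothelial (0.0659) lists did not pass. The Kupffer list did not pass without exercised library 1 (0.0614) or 5 (0.0872) either.

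The count of 648 genes fell by more than 1.5-fold without sedentary library 1 (418), 2 (342) or 5 (367) and without exercised library 1 (360) or 4 (418). Of 65 named genes that passed, 42 still passed in each of the 10 fits that left out a library, and 0 changed direction.

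The second comparison set gap-matched against sedentary rats, neither of which had exercised, and so addresses the diet after weight loss. Of the tested members, 13 of 19 were lower in the lipogenesis, 4 of 13 in the glycolysis, 5 of 9 in the pentose phosphate and 5 of 15 in the heat shock list. Each of the 4 lists had an adjusted p = 0.0748 with an estimated correlation. Fasn fell by 1.76 ± 0.26, from 1170 ± 272 to 359 ± 131 FPKM (limma adjusted p = 0.00408), and all 5 gap-matched libraries lay below the lowest sedentary library. Scd1, the stearoyl-CoA desaturase, fell by 1.19 ± 0.22 (limma adjusted p = 0.011), and Acaca, the acetyl-CoA carboxylase, by 0.88 ± 0.17 (0.0118). Of the 11216 genes 92 were higher and 250 lower at a limma adjusted p under 0.05, and 14 of the higher and 26 of the lower differed by more than 2-fold. Lower genes made up 73.1% of these calls, but 58.9% after median-of-ratios scaling, 59.7% after quantile normalization and 83.9% after scaling to the same sum.

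Of 19 lipogenesis members 13 fell, 0 rose and the others did not pass, and 15 were lower when adjusted over the list alone. The median was −0.88 and the camera adjusted p 4.6e-14, with an adjusted p = 0.0748 with an estimated correlation. Gpam fell by 2.24 ± 0.31, Pnpla3 by 1.54 ± 0.31, Elovl6 by 1.43 ± 0.29, Acly by 1.07 ± 0.21 and Pklr by 1.04 ± 0.19. Mlxipl, the carbohydrate-responsive factor, fell by 0.63 ± 0.13 (limma adjusted p = 0.0144). Me1, the cytosolic malic enzyme, fell by 1.66 ± 0.37 (limma adjusted p = 0.0253), a call lost in 5 of the 10 fits that left out a library, at up to 0.0678. Srebf1 fell by 0.67 ± 0.16 (limma adjusted p = 0.0306), a call lost in 7 of these fits, at up to 0.0857, and after quantile normalization (0.0533). Pck1 differed by 1.04 (limma adjusted p = 0.207) and Cpt1a by 1.01 (0.0551), and neither passed.

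Of 24 cholesterol genes 3 fell, and adjusted over the list alone 7 were lower and 1 higher. Acat2 fell by 1.08 ± 0.20, Mvd by 0.90 ± 0.18 and Pmvk by 0.79 ± 0.15. The median was −0.31 and the camera adjusted p 8.8e-05, with an adjusted p = 0.423 with an estimated correlation. In the pentose phosphate list 5 of 9 fell, and adjusted over the list alone 6 were lower and 1 higher. The transketolase Tkt fell by 0.78 ± 0.15 and the transaldolase Taldo1 by 0.57 ± 0.08. That list had a median of −0.57, a camera adjusted p of 0.000664 and an adjusted p = 0.0748 with an estimated correlation. In the glycolysis list 4 of 13 fell and 9 were lower when adjusted over the list alone, with Eno1 down by 0.65 ± 0.13 and Gapdh by 0.61 ± 0.11. Its median was −0.34 and its camera adjusted p 5.2e-06, with an adjusted p = 0.0748 with an estimated correlation. Of 26 triglyceride and lipid droplet genes 4 fell and 9 were lower when adjusted over the list alone. Plin2 fell by 1.20 ± 0.20 and Tm6sf2, which takes part in lipoprotein export, by 0.91 ± 0.15. The median was −0.22 and the camera adjusted p 0.00931, with an adjusted p = 0.423 with an estimated correlation. Of 21 genes of the tricarboxylic acid cycle 3 fell and 7 were lower when adjusted over the list alone. Dlat, a subunit of pyruvate dehydrogenase, fell by 0.95 ± 0.16. This list had a median of −0.17, a camera adjusted p of 0.000211 and an adjusted p = 0.0964 with an estimated correlation.

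Of 15 heat shock genes 5 fell and 8 were lower when adjusted over the list alone, with a median of −0.44. The camera adjusted p was 3.5e-06, with an adjusted p = 0.0748 with an estimated correlation. Each named member lost its call in some fits that left out a library. Hspa4l fell by 0.85 ± 0.18 (limma adjusted p = 0.02), and its call was lost without sedentary library 5 (0.0538), gap-matched library 1 (0.0519) or 5 (0.0528). Of 14 immediate early genes 2 fell and 4 were lower when adjusted over the list alone, among them Jund by 0.60 ± 0.11. The median was −0.43 and the camera adjusted p 0.0121, which did not pass without sedentary library 1 (0.0914) or gap-matched library 3 (0.0802), and the adjusted p = 0.423 with an estimated correlation.

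Fewer genes rose. The metallothionein MT1 rose by 2.27 ± 0.33, from 3.51 ± 1.11 to 22.4 ± 12.3 FPKM, with the same limit on shared reads. Hsd17b2, which oxidises estradiol and testosterone, rose by 1.39 ± 0.22, from 272 ± 74.2 to 710.5 ± 185 FPKM (limma adjusted p = 0.00603). Fabp7, a fatty acid binding protein, rose by 1.67 ± 0.35, from 58.8 ± 25.8 to 184 ± 65.5 FPKM, and the bile acid and drug transporter Slco1a4 by 1.13 ± 0.17. Enpp2, the enzyme autotaxin, rose by 0.92 ± 0.13, from 53.0 ± 12.6 to 99.0 ± 3.08 FPKM. Of 16 bile acid genes 1 rose and 7 were higher when adjusted over the list alone. The median was 0.19 and the camera adjusted p 0.000211, with an adjusted p = 0.0869 with an estimated correlation. Slc10a1, the bile acid uptake carrier, rose by 0.46 ± 0.10, a call lost without sedentary library 5 (limma adjusted p = 0.0516) or gap-matched library 1 (0.052). Of 35 drug and steroid metabolism genes 2 rose, and adjusted over the list alone 3 were higher and 1 lower. Cyp3a23/3a1 rose by 0.77 ± 0.14. The median was 0.13 and the camera adjusted p 0.000293, with an adjusted p = 0.0748 with an estimated correlation.

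Ribosomal protein transcripts had a median of 0.18 with 0 of 70 passing, and a camera adjusted p of 0.000211, with an adjusted p = 0.704 with an estimated correlation. Erythroid markers moved in the same direction, with a median of 0.45, 0 of 4 passing, a camera adjusted p of 0.0119 and an adjusted p = 0.423 with an estimated correlation. Kupffer cell markers had a median of 0.20, 0 of 13 passing, a camera adjusted p of 0.00793 and an adjusted p = 0.53 with an estimated correlation. Pericentral markers had a median of 0.27 with 1 of 12 higher, also over the list alone, a camera adjusted p of 0.0119 and an adjusted p = 0.425 with an estimated correlation. The member was Rnase4, which rose by 0.85 ± 0.14. Acute phase genes had a median of 0.09 with 1 of 23 higher, also over the list alone, and a camera adjusted p of 0.0364. That call did not pass after quantile normalization (0.545) or median-of-ratios scaling (0.0566), nor without sedentary library 5 (0.507) or gap-matched library 3 (0.0708) or 4 (0.131), and the adjusted p = 0.53 with an estimated correlation. The erythroid list did not pass without sedentary library 3 (camera adjusted p = 0.0529), nor the Kupffer list without sedentary library 5 (0.247). The pericentral list did not pass without sedentary library 5 (0.168) or gap-matched library 1 (0.0509). The gluconeogenesis list did not pass, with a median of −0.02, a mean of 0.11 and a camera adjusted p of 0.3.

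The count of 342 genes fell by more than 1.5-fold without sedentary library 2 (147), 3 (186) or 5 (178) and without gap-matched library 1 (202), 2 (192), 4 (220) or 5 (213). Of 65 named genes that passed, 39 still passed in each of the 10 fits that left out a library, and 0 changed direction.

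The 2 comparisons with sedentary rats share the sedentary libraries, so their differences were set against simulated unchanged groups. In both comparisons 123 genes were lower, where 8.16 would be shared by independent lists of these sizes, and 39 were higher, where 2.31 would be shared. Only 1 gene was called in opposite directions. Simulated unchanged groups gave 0 genes called in both with the same sign. Across genes, which are not independent replicates, the correlation of the differences was 0.592 against a simulated mean of 0.489 and a highest of 0.782. The covariance was 0.0437 against a mean of 0.0176, a difference of 0.0262, and a highest of 0.0451, so both lay within the simulated spread. With separate sedentary libraries for each comparison, the correlation averaged 0.295 over 20 divisions, between 0.161 and 0.413, and 5 of 100 simulations of unchanged groups gave as high an average.

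**Figure D2:**
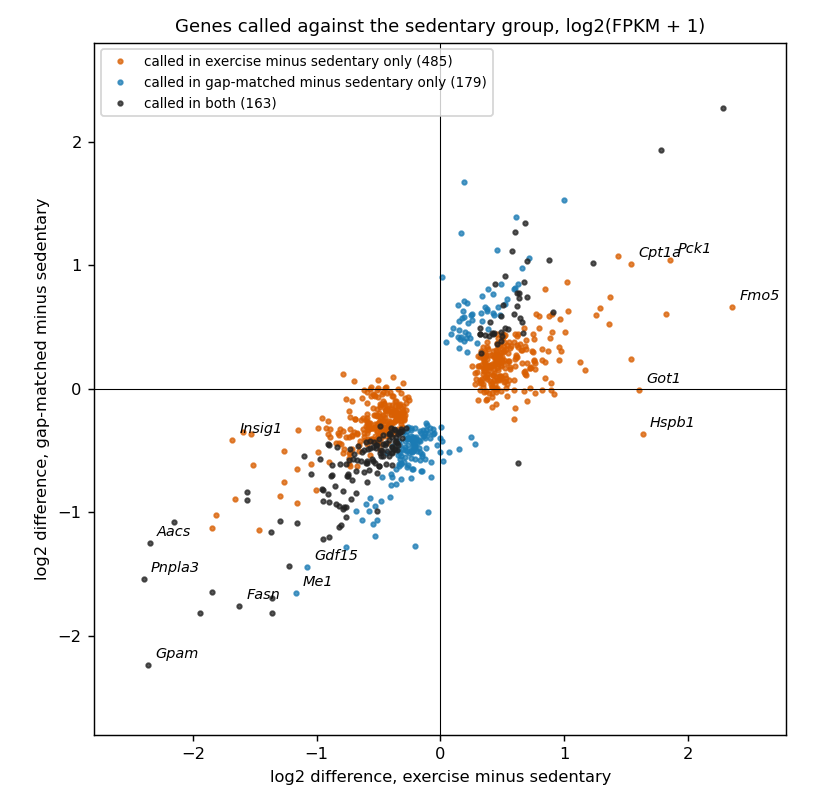
Log2 differences of genes that passed in at least 1 comparison with sedentary rats, exercised on the x axis and gap-matched on the y axis, 1 point per gene. There were 485 genes that passed for exercised rats only, 179 for gap-matched rats only and 163 for both, of which 162 went the same way, and part of the likeness comes from the shared sedentary libraries.

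The third comparison set exercised directly against gap-matched rats, which tests how the exercised and the gap-matched groups differ from each other. In exercised rats 3 of 15 heat shock, 1 of 36 amino acid and 1 of 12 gluconeogenesis genes were higher and 2 of 24 cholesterol genes lower, while no lipogenic gene of the panel passed. Each of these 4 lists passed with the preset correlation, with an adjusted p = 0.667 with an estimated correlation. Hspb1 was 98.9 ± 47.6 FPKM in exercised and 22.5 ± 4.30 FPKM in gap-matched rats, a rise of 2.0 ± 0.24 (limma adjusted p = 0.000972), with all 5 exercised libraries above the highest gap-matched library. Got1 rose by 1.62 ± 0.23, from 102 ± 28.9 to 319 ± 101 FPKM (limma adjusted p = 0.00369), and Slc25a15 by 1.02 ± 0.11, from 109 ± 10 to 223 ± 27.2 FPKM (0.000749). Of the 11216 genes 77 were higher and 24 lower at a limma adjusted p under 0.05, and 5 in each direction differed by more than 2-fold. Lower genes made up 23.8% of these calls, but 40.7% after median-of-ratios scaling, 36.6% after quantile normalization and 17.6% after scaling to the same sum.

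In the lipogenesis list 0 of 19 members passed, by the all-gene test or over the list alone. The median was 0.01 and the mean 0.03, with a camera adjusted p of 0.892 in the downward direction, and the median turned negative after median-of-ratios scaling (−0.04) and quantile normalization (−0.02). Fasn differed by 0.13 ± 0.26 (limma adjusted p = 0.843), Acly by −0.22 ± 0.21 (0.608) and Scd1 by 0.67 ± 0.22 (0.158). Of 24 cholesterol genes 2 fell and 8 were lower when adjusted over the list alone, with a median of −0.23. The camera adjusted p was 4.0e-08, with an adjusted p = 0.667 with an estimated correlation. The members were Insig1, which fell by 1.27 ± 0.28 (limma adjusted p = 0.0484), and Sqle, which fell by 0.76 ± 0.16 (0.0418). Each lost its call in 9 of the 10 fits that left out a library, Insig1 at up to 0.143 and under all 3 scalings, and Sqle at up to 0.113 and after scaling to the same sum. Sgk2 fell by 1.08 ± 0.15, from 14.2 ± 3.88 to 6.03 ± 0.616 FPKM (limma adjusted p = 0.00371), and Hes6, a transcriptional regulator, by 0.82 ± 0.12 (0.00542). Aacs fell by 1.10 ± 0.21 (limma adjusted p = 0.0288), a call lost without exercised library 2 (0.0562) or gap-matched library 2 (0.0807) or 4 (0.0706).

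Of 15 heat shock genes 3 rose and 0 fell, and adjusted over the list alone 6 were higher and 1 lower. The median was 0.17 and the mean 0.38, and camera gave an adjusted p of 0.00905, with an adjusted p = 0.667 with an estimated correlation. Hsph1, a co-chaperone of the Hsp70 family, rose by 1.23 ± 0.16, from 22.8 ± 3.79 to 55.1 ± 11.3 FPKM (limma adjusted p = 0.00142). Hsp90ab1 rose by 0.64 ± 0.11 (limma adjusted p = 0.021), a call lost in 4 of the 10 fits that left out a library, at up to 0.0712. Mapkapk2, a kinase that phosphorylates Hspb1, rose by 0.84 ± 0.09, from 21.4 ± 2.90 to 39.1 ± 2.70 FPKM (limma adjusted p = 0.000749).

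**Figure D3:**
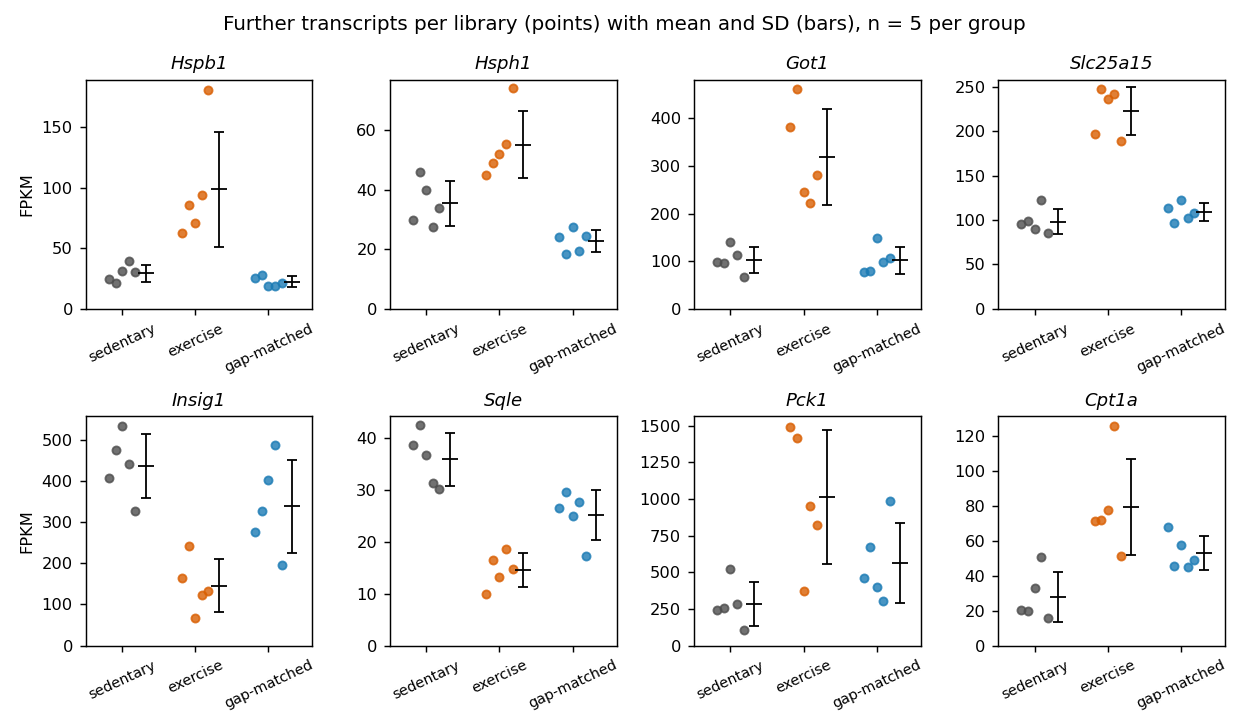
FPKM of 8 genes in each of the 15 libraries, by group, with the mean and SD of 5 libraries. Hspb1, Hsph1, Got1 and Slc25a15 passed as higher in exercised than in gap-matched rats, at means of 98.9, 55.1, 319 and 223 FPKM against 22.5, 22.8, 102 and 109 FPKM.

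Among 36 genes of amino acid breakdown and the urea cycle 1 rose, Slc25a15, and 8 were higher when adjusted over the list alone, with a median of 0.20. The camera adjusted p was 0.000102, with an adjusted p = 0.667 with an estimated correlation. In the gluconeogenesis list 1 of 12 rose, Got1, and 2 were higher when adjusted over the list alone, with a median of 0.30 and a camera adjusted p of 0.0176. The adjusted p = 0.667 with an estimated correlation, and the call was lost without exercised library 1 (0.0612) or 2 (0.0839). Pck1 differed by 0.82 ± 0.42 (limma adjusted p = 0.351) and Cpt1a by 0.53 ± 0.27 (0.34). Of 21 tricarboxylic acid cycle genes 2 rose and 6 were higher when adjusted over the list alone, with a median of 0.17. The camera adjusted p was 0.000102, with an adjusted p = 0.501 with an estimated correlation. Fh, the fumarate hydratase, rose by 0.45 ± 0.08 (limma adjusted p = 0.0184, and 0.0503 without gap-matched library 2). In the fatty acid oxidation list 0 of 34 passed and 6 were higher when adjusted over the list alone, with a median of 0.19. The camera adjusted p was 0.00223, with an adjusted p = 0.667 with an estimated correlation.

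Ribosomal protein transcripts had a median of −0.29 with 0 of 70 passing, and a camera adjusted p of 3.8e-09, with an adjusted p = 0.667 with an estimated correlation. Cell cycle genes had a median of −0.30 with 0 of 11 passing, a camera adjusted p of 0.000123 and an adjusted p = 0.667 with an estimated correlation. Erythroid markers moved in the same direction, with a median of −0.51, 0 of 4 passing, a camera adjusted p of 0.00846 and an adjusted p = 0.667 with an estimated correlation. Periportal markers had a median of 0.45 with 1 of 14 higher and 5 when adjusted over the list alone. Their camera adjusted p was 0.0335, with an adjusted p = 0.667 with an estimated correlation, and the call was lost without exercised library 1 (0.0841) or 2 (0.0769) or gap-matched library 1 (0.097) or 5 (0.0503).

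Several of these lists also varied together among libraries of 1 group. Over the 15 libraries, with group means removed, the mean of the ribosomal list correlated with that of the gluconeogenesis list at Pearson's r = −0.82 (permutation p = 0.00089) and Spearman's rho = −0.87 (permutation p = 0.00058). The r was −0.94 in sedentary, −0.79 in exercised and −0.80 in gap-matched rats, and −0.78 without the 2 libraries farthest from the median. The Benjamini-Hochberg adjusted permutation p over 31 such relations was 0.00608. The erythroid list correlated with it at r = −0.82 (permutation p = 0.0024) and rho = −0.73 (permutation p = 0.00717), with r = −0.75 without the 2 farthest libraries and an adjusted permutation p of 0.0124. By group its r was −0.83 in sedentary, −0.92 in exercised and −0.39 in gap-matched rats.

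The count of 101 genes fell by more than 1.5-fold without exercised library 1 (34), 2 (20) or 4 (22) and without gap-matched library 2 (18), 4 (26) or 5 (23). Of 30 named genes that passed, 10 still passed in each of the 10 fits that left out a library, among them Hspb1, Hsph1, Got1, Slc25a15, Rtn4rl1, Mapkapk2, Sgk2, Hes6 and Usp1.

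**Figure D4:**
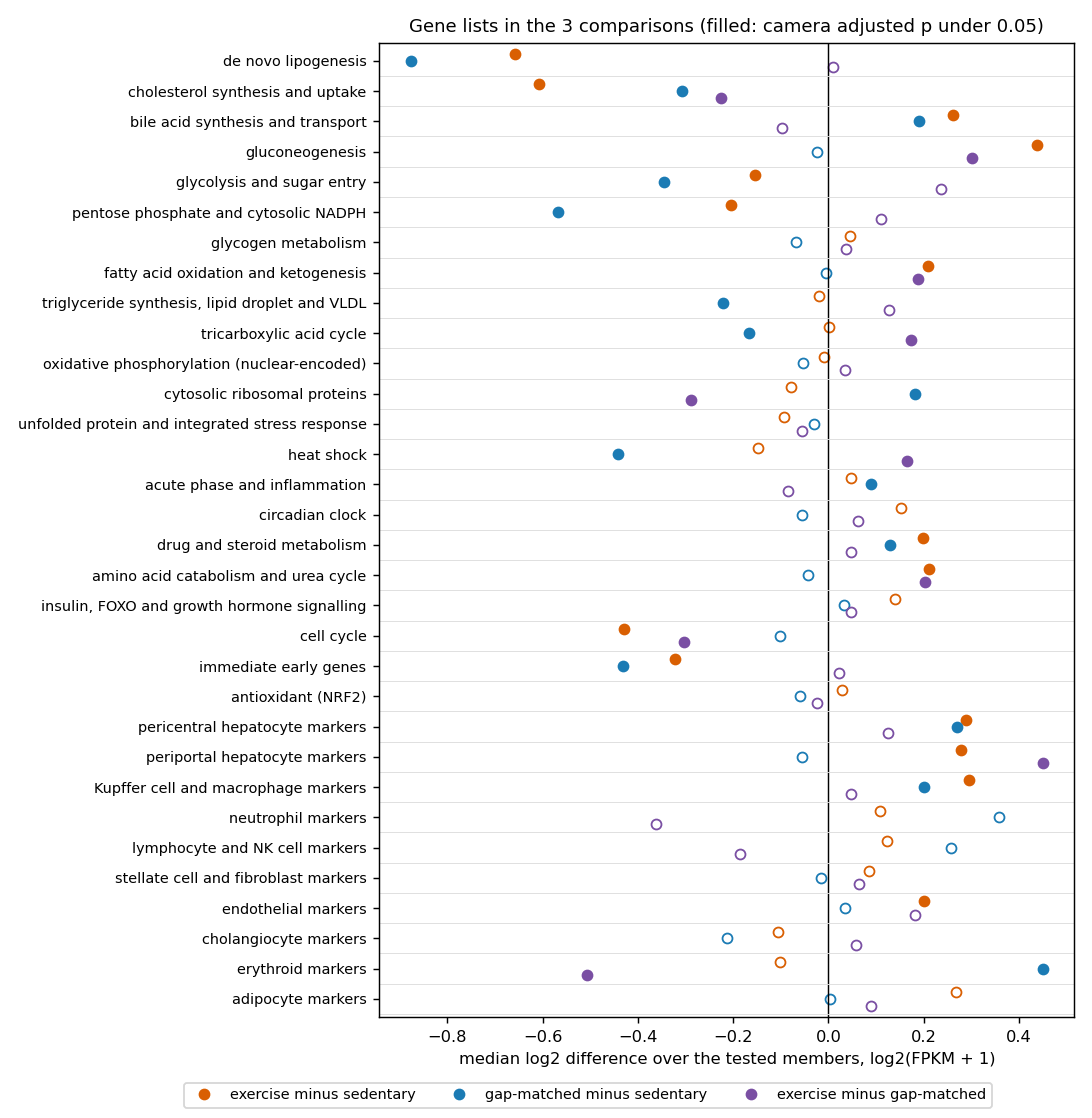
Median log2 difference of the tested members of each gene list in the 3 comparisons, filled where camera with the preset correlation gave an adjusted p under 0.05. The lipogenesis list had medians of −0.66 in exercise minus sedentary, −0.88 in gap-matched minus sedentary and 0.01 in exercise minus gap-matched, the last turning negative under median-of-ratios and quantile scaling, and no list passed with an estimated correlation.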

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

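The tests of stress at collection, of chance levels of the sedentary libraries and of a bias against short transcripts were chosen only after the result was seen. Of 201 groups of 5 libraries of the named genes, 6 held a library whose gap to the nearest other exceeded Dixon's 95% limit, and chance flags about 1 in 20 groups. Sedentary library 4 was the lowest of its group for Fasn, with a gap of 0.714 of the range, and for Pnpla3, with 0.717, and the highest for Enpp2, with 0.726. For 2010003K11Rik sedentary library 5 was the highest, at 0.770 of the range. Exercised library 3 was the highest for Mrps10, at 0.851. Exercised library 2 was the lowest for Retsat, at 0.852.

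Of 19 lipogenic transcripts 11 were lower in exercised and 13 in gap-matched than in sedentary rats (list adjusted p = 0.104 and 0.0748 with an estimated correlation), and sedentary library 4 stood apart for 2 of them. Library scaling as the cause is argued against, since at least 9 of the 11 lipogenesis members called in exercise minus sedentary stayed called under each of 3 other scalings, and so is a single outlying sedentary library, since that list's median closest to 0 without 1 of them was −0.62. Chance levels of the sedentary libraries are argued against too, since with separate sedentary libraries for each comparison the list's median closest to 0 was −0.57, and 0 of 100 simulations of unchanged groups reached it. Across all genes, a likeness made by the shared sedentary libraries cannot be told apart with certainty from a common change. With separate libraries the lowest correlation was 0.161, which 3 of 100 simulations of unchanged groups reached, the highest at 0.205. The bound of 0.1 set in advance had left out that spread. What stays open is whether the 2 groups share a biological route to lower transcripts, which the design does not test.

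Of 15 heat shock members 3 were higher in exercised than in gap-matched rats, while the list had an adjusted p = 0.667 with an estimated correlation and 0.0847 in the exact permutation test. The unadjusted p of that permutation test was 0.00794, the smallest it can give with these libraries, so its adjusted value depends on the other lists. Scaling does not account for these 3, since all stayed called under each of 3 other scalings, and 1 library does not account for Hspb1 and Hsph1, since at least 0.878 of their log2 difference remained without any 1 library, whereas Hsp90ab1 lost its call in 4 of the 10 fits. As a list, the difference lay in a lower level in gap-matched rats. The list's mean differed by 0.376 in exercise minus gap-matched, −0.444 in gap-matched minus sedentary and −0.068 in exercise minus sedentary. Its median was −0.44 in gap-matched minus sedentary, where camera passed (adjusted p = 0.0748 with an estimated correlation). It was −0.15 in exercise minus sedentary, where camera did not pass (adjusted p = 0.25). Of the 3 members, Hspb1 and Hsph1 also passed as higher in exercised than in sedentary rats, Hsph1 with a call lost in 5 of 10 fits. Hsp90ab1 had means of 643 FPKM in sedentary, 715 in exercised and 456 in gap-matched rats. For the list as a whole, a rise in exercised rats, from exercise or from stress at collection, is argued against by these means. For Hspb1 and Hsph1, stress or handling at collection could raise transcripts in 1 group and cannot be told apart from exercise here. The immediate early list gave a camera adjusted p of 0.892, and a test that does not pass decides nothing. For Hspb1 and Hsph1 the exercise history and the diet, which differ together between these groups, both stay open. For the list, causes that lower it in gap-matched rats, the diet among them, stay open.

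Ribosomal protein transcripts were lower in exercised than in gap-matched rats as a list, although 0 of 70 passed singly and the list had an adjusted p = 0.667 with an estimated correlation. No transcript lengths were at hand, and the nuclear-encoded oxidative phosphorylation list was taken to hold short transcripts as well. On that footing, a bias against short transcripts as the whole cause is argued against by this list. Its median difference was 0.0349 (quartiles over members −0.10 to 0.16), and its mean difference was 0.026 with a standard error over libraries of 0.102. The ribosomal mean differed from it by −0.275 (exact permutation p = 0.0159, unadjusted). That standard error leaves room for such a bias as part of the cause. Spread between single libraries may account for the difference, since the exact permutation test of the list's mean per library gave a two-sided p of 0.1825. The same list varied within groups, as described for its relation with the gluconeogenesis list, which the preset correlation of camera does not take in.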

How the results depend on the processing

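The covariate from deviations within groups and the exact permutation of list means were chosen only after the result was seen. No named gene that passed, and no list that passed, changed direction under the alternatives tried for it, which were 28 for the lipogenesis list and 18 for each other list. The filters, the settings of the trend, the fits of only the 2 groups, the block and the covariate leave a gene's difference as it is. They could not change its direction, and an estimated correlation could not change that of a list. Only the other alternatives bear on direction. The count of 648 genes in exercise minus sedentary was 1108 at an adjusted p under 0.1 and 1238 with the covariate, and 342 to 642 without 1 library. The count of 342 in gap-matched minus sedentary became 653 and 909 under the same settings, and 147 to 357 without 1 library. The count of 101 in exercise minus gap-matched became 272 and 772, and 53 with no filter on low values, where more genes were tested. It was 34 with libraries rescaled to the same sum, 16 in a fit of only the 2 groups compared, which holds fewer samples, and 18 to 131 without 1 library. The covariate was made from the deviations of these same libraries, so it lowers the spread that is left by construction. The higher counts with it are therefore no evidence of more differing genes. Apart from the filter, the smaller fits, the threshold and the covariate, the cause was not tested.

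The lipogenesis list kept its direction in both comparisons with sedentary rats. With an estimated correlation its median of −0.66 in exercise minus sedentary had a camera adjusted p of 0.1045, and its median of −0.88 in gap-matched minus sedentary one of 0.0748. The directional fry test asks whether the members differ at all, not whether they differ more than other genes. It gave the list adjusted p-values of 0.0015 in exercise minus sedentary, 0.000529 in gap-matched minus sedentary and 0.886 in exercise minus gap-matched. In the exact permutation test, the difference of list means of −0.86 in exercise minus sedentary had p = 0.00794, the smallest that 5 against 5 libraries can give, and an adjusted p of 0.0508. That of −0.89 in gap-matched minus sedentary had the same p and passed, at an adjusted p of 0.0363. Without 1 library the medians ran from −0.69 to −0.53 in exercise minus sedentary, −0.97 to −0.73 in gap-matched minus sedentary and −0.06 to 0.11 in exercise minus gap-matched.

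With the replicate number as a block, 449, 201 and 20 genes passed in the 3 comparisons, in the order above, and no list call changed. Libraries with the same number did not deviate together, with correlations from −0.27 to 0.13, −0.08 to 0.19 and −0.23 to 0.08. Own numbers correlated best in 1, 1 and 0 of 5 pairs, so the numbers do not pair the samples. Of the 65, 65 and 30 named genes that passed, 9, 7 and 12 lost their call under at least 1 scaling, 23, 26 and 20 without at least 1 library and 9, 15 and 18 under the block. Absolute depth is unknown, so counting error for genes of low FPKM could not be given.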

Other observations

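The tests of relations between lists within groups and of a component behind them were chosen only after the result was seen. Genes of the unfolded protein and integrated stress response went both ways in exercised against sedentary rats, with 5 of 25 lower and 1 higher, also over the list alone, and the list did not pass (median −0.09, camera adjusted p = 0.161). Pdia4, a disulfide isomerase of the endoplasmic reticulum, fell by 0.51 ± 0.09 and the transcription factor Atf4 by 0.44 ± 0.08, while XBP1, a transcription factor of the unfolded protein response, rose by 0.74 ± 0.16 (limma adjusted p = 0.00432, 0.00751 and 0.0145). In gap-matched against sedentary rats Atf4 fell by 0.44 ± 0.08 as well (limma adjusted p = 0.0118), 1 of 2 lower members (3 over the list alone) of a list that did not pass (median −0.03, camera adjusted p = 0.835). Of 23 insulin and growth hormone signalling genes 2 rose and 1 fell in exercised against sedentary rats, and adjusted over the list alone 4 were higher and 3 lower, while the list did not pass (median 0.14, camera adjusted p = 0.282). In gap-matched against sedentary rats 1 fell, also over the list alone, and the list did not pass either (median 0.03, camera adjusted p = 0.413). The kinase Akt1 fell by 0.42 ± 0.09 in exercised and by 0.42 ± 0.09 in gap-matched rats against sedentary (limma adjusted p = 0.012 and 0.0181). Socs2, an inhibitor of growth hormone signalling, rose by 1.82 ± 0.44 in exercised rats, from 3.60 ± 2.68 to 14.1 ± 5.99 FPKM (limma adjusted p = 0.0229), a call lost in 4 of the 10 fits that left out a library, at up to 0.0583. Irs1, an insulin receptor substrate, rose by 0.44 ± 0.12 (limma adjusted p = 0.0444), a call lost in 8 of these fits, at up to 0.111, and after scaling to the same sum (0.0895).

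Among clock genes, Nfil3, a clock-controlled repressor, rose by 1.08 ± 0.20 in exercised against gap-matched rats (limma adjusted p = 0.0267). The call was lost in 5 of the 10 fits that left out a library, at up to 0.0712. Of 15 tested members of the circadian list 2 rose and 3 were higher when adjusted over the list alone, and the list as a whole did not pass (median 0.06, camera adjusted p = 0.633).

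Other divisions of the same libraries were drawn, 100 of 126 for each comparison. For exercise minus sedentary 1 of the 100, the real one, gave as many as 648 genes and the highest other gave 1. For gap-matched minus sedentary 1 of the 100, the real one, gave as many as 342 and the highest other gave 5. The divisions drawn argue against chance in these 2 comparisons, but do not exclude it, since not all were drawn. For exercise minus gap-matched 2 of the 100, the real one included, gave as many as 101 genes, and the highest other gave 624. A division that mixes the groups can thus give more calls than the groups do, so chance is not excluded for this comparison. That division set exercised libraries 1, 2 and 4 with gap-matched libraries 1 and 3 against the rest. It is the division by sign of the first component of the deviations within groups, over all tested genes. The component was 2.85 to 21.3 in the libraries named and −20.2 to −3.96 in the rest. The division thus follows a structure that remains after group means are removed, and no label says what it is. In exercise minus sedentary the sign of that component also divides the libraries evenly. It sets sedentary libraries 3 and 4 with exercised libraries 1, 2 and 4, and whether that division was among those drawn was not recorded.

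A hypothesis is that rats of 1 group differ along a single axis that holds the gluconeogenesis and ribosomal lists. The first component within groups of the 11134 genes in neither list correlated with the ribosomal mean at r = −0.955 and with the gluconeogenesis mean at r = 0.858 (permutation p = 1e-05 and 5e-04). No other list was set against that component. With the gluconeogenesis mean itself, the means of periportal markers (r = 0.95), amino acid breakdown (r = 0.91) and the circadian list (r = 0.78) correlated within groups. Members shared with the gluconeogenesis list were left out. The periportal and amino acid lists still share members with each other, such as Cps1, Ass1 and Otc, so their relations are not separate. The oxidative phosphorylation list, also taken to hold short transcripts, correlated negatively with the gluconeogenesis mean (r = −0.85), as the ribosomal list did. A bias by transcript length could thus give part of these relations and stays open. In the order periportal, amino acid, circadian and oxidative phosphorylation, Spearman's rho was 0.87, 0.82, 0.75 and −0.87, and r without the 2 farthest libraries was 0.90, 0.89, 0.80 and −0.81. The permutation p-values of r were 7e-05, 0.00012, 0.00098 and 0.00065, those of rho 0.00015, 0.00087, 0.00523 and 0.00062, and the adjusted ones of r 0.00186, 0.00186, 0.00608 and 0.00608 over 31 relations. By contrast, the lipogenesis list had, with the gluconeogenesis mean, r = −0.02 (permutation p = 0.953) and rho = 0.01 (permutation p = 0.976). The time since the last meal or of collection may differ between rats of 1 group, which no label gives, so this was not tested.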
